A study of Mus musculus with 12 samples.

How the data were processed

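Messenger RNA was sequenced from the livers of 12 C57BL/6J mice, and the values used here are those that the authors deposited; raw reads were not used here. Per the labels' protocols, mice aged 9 months were fed a purified chow with 0, 1 or 5% (w/w) of a fish oil concentrate rich in very-long-chain polyunsaturated fatty acids (VLCPUFA) for 8 weeks. Livers were taken after a fast of 5 hours, RNA with an integrity number above 7 was kept, and libraries came from a stranded poly(A) kit. The labels name 4 libraries per diet, 2 from females and 2 from males, while the series design text speaks of 6 samples per diet; only the 12 libraries were analysed. Replicate names are animal numbers that no group shares, so no pairing was used.

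The deposited gene table holds estimated counts for 49398 Ensembl genes, and a further deposited table holds estimated counts for 141450 transcripts; kallisto, edgeR and limma are named without versions or roles in the submitters' processing notes, with the mouse build GRCm39. Of the cells of the gene counts, 11.7% are not whole numbers, and for 99.3% of the 48897 genes present in both tables the gene value lay within 1 read of the sum of its transcripts. The deposited CPM table gives 11339 genes as CPM, computed, as its values show, over those genes alone and with no TMM factor. The authors also deposited a table of 261 genes with a log2 fold change, a p-value and an adjusted p-value per gene; per the file headers these are their test's output, and the contrast is not named there. That deposited table also holds CPM-like values per library from which the difference between the sexes had been taken out on a log scale, a step no label describes; they were used in no test. Symbols came from a reference gene table: 48845 IDs matched and 553 did not, and no coordinates are given because that table's build differs from the one named by the authors. Whether counting used the strand of the reads is not stated, so values of antisense and overlapping genes are uncertain. Reads of near-identical copies, among them the Cyp3a, Cyp4a, Cyp2a, Gstm, Gsta, Saa and Mup families, are shared out by estimation, so values of single members are uncertain.

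Library totals ran from 5291385 to 15674130 estimated reads. Estimated counts were rounded to whole numbers and analysed in R 4.3.3 with edgeR 4.0.16: filterByExpr on the 6 groups of diet and sex kept 13814 genes, TMM factors scaled the libraries, and a robust quasi-likelihood fit with diet as a factor and sex as an additive term gave a common biological coefficient of variation of 0.266. All 12 libraries entered each fit, so that the diets share an estimate of the spread. The contrasts were 5% against control, 1% against control, 5% against 1%, and female against male; the dose trend used the percent of oil as a number. A fit with the 6 groups gave the 5% comparison within each sex and the differences between the sexes in the response to each dose. Adjusted p values are Benjamini-Hochberg values of edgeR's 2-sided quasi-likelihood test over the genes tested, with a threshold of 0.05. Errors of log2 fold changes are standard errors, computed as the size of the log2 fold change over the square root of the F statistic. CPM in the text, except those of long noncoding genes and of the Lars2 transcript, are scaled by the TMM factors and given with the SD over libraries. Standard errors hold the spread between animals and counting error, which is large for genes of few reads, and intervals for counts cover counting error only.

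Gene lists (45, of which 41 had at least 5 tested members) were tested with camera from limma 3.58.1 at a preset correlation of 0.01 on log2 CPM with a prior count of 2, 2-sided and adjusted over the lists; an estimated correlation and fry were run beside it. Of the list symbols 3 matched no gene. Set test p values in the text are camera's unless fry is named. Counts per list are given over all genes tested and adjusted over the list alone. The rule for named genes took, per diet comparison, the 10 largest increases and 10 largest decreases among genes past the threshold with a mean log2 CPM of at least 1 and the same sign in both sexes, leaving out unnamed predicted genes. For 5% against control it added up to 4 members per list by smallest p, and for both doses against control a fixed set of genes of lipid metabolism, inflammation and oxidative stress whatever their result. For the sexes it took the 5 largest in each direction, the Y-linked genes and Xist, and where fewer than 5 genes passed it took the 5 with the smallest p as values. The design, the lists, this rule and the alternatives, except those stated as added, were set before the data were examined.

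The alternatives were other scaling factors (RLE, upper quartile), no filter and a stricter filter (50 reads in 4 libraries), DESeq2 1.42.0, limma voom, limma trend on the deposited CPM with a pseudocount of 0.5, sums of transcript counts, other covariates, a surrogate variable from sva 3.50.0, an adjusted p of 0.1, a 2-fold minimum, and each library left out in turn. Added after the data were seen were the contrast of both oil diets against control, the share of long noncoding reads or a score of clock genes as a covariate, and fits on the 6 libraries below or above a noncoding share of 0.8%. For the clock score, log2 CPM were standardized per gene and averaged. The mean of Arntl, Npas2, Clock, Cry1 and Nfil3 was subtracted from that of Dbp, Tef, Hlf, Nr1d1, Nr1d2, Per3, Ciart and Bhlhe41. Where a library left out leaves a group of diet and sex with 1 animal, that animal is assumed to vary like the others.

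The tests were tried on simulated counts with genes changed by known folds. For 5% against control the edgeR test found 37.8% of genes changed 2-fold and 83% of genes changed 4-fold, with 8 false calls among 128. For 1% against control it found 34.7% and 81.8% at those folds, for 5% against 1% 37.4% and 79%, for the trend 43.4% and 86.6%, for the sexes 58.6% and 89.9%, and for both oil diets against control 48.5% and 90.5%. For the 5% comparison in females it found 5.05% and 52.5%, and in males 4.08% and 56%. For the difference between the sexes in the response it found 0% of genes whose response differed 2-fold and 16% at 4-fold for the 5% diet, and 0% and 6% for the 1% diet. DESeq2 made 27 false calls in the simulated 5% comparison, against 8 for edgeR and 5 for limma voom. Of 41 simulated lists, camera called the 1 that was changed and 0 of 40 others. Genes were simulated independently of each other, so this does not show how often camera calls an unchanged list of correlated genes. A shared effect variance of 0.09 between the doses was recovered as 0.0908.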

Results

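The 12 livers came from mice fed a chow with no VLCPUFA oil (control, 4 animals), with 1% oil (4 animals) or with 5% oil (4 animals), each diet given to 2 females and 2 males. VLCPUFA are fatty acids longer than the usual omega-3 fatty acids of fish oil. Animals are named by diet, sex and number: control females N979 and N980, control males N967 and N968, 1% females N983 and N984, 1% males N971 and N972, 5% females N987 and N988, and 5% males N975 and N976. Depth ran from 5291385 estimated reads in control female N979 to 15674130 in 5% male N976. The other controls had 11132269 (N980), 10488365 (N968) and 6594318 (N967) reads. The 1% livers had 6275571 (N984), 12317219 (N983), 11122698 (N972) and 11680742 (N971), and the other 5% livers 11983330 (N988), 14964983 (N987) and 8723052 (N975). The Y-linked gene Eif2s3y had 0 reads over the females and 2563 over the males, at least 824-fold higher in males against a floor of 3 reads over the group. Xist had 39250 reads over the females and 7 over the males, so each library's sex label held. Libraries of the same group correlated at r = 0.93 for the control females and from 0.959 to 0.97 for the other groups, across genes, which are not independent replicates.

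The 5% diet against control asks what the higher dose does in the liver. Several genes of fatty acid oxidation that the receptor PPARα controls rose. Acot1, an acyl-CoA thioesterase, went from 17.9 ± 5.16 to 97.1 ± 8.15 CPM (mean ± SD, n = 4 per diet), a log2 fold change of 2.46 ± 0.18 (edgeR adjusted p = 3.62e-05). The fatty acid omega-hydroxylases Cyp4a10 and Cyp4a14 rose by 2.56 ± 0.26 and 2.57 ± 0.29 on the log2 scale, and the peroxisomal enzyme Ehhadh by 2.34 ± 0.24. Gstm1, a glutathione transferase, went from 2058 ± 374 to 8594 ± 1907 CPM (log2 fold change 2.09 ± 0.23, edgeR adjusted p = 0.000387). Nqo1, a quinone reductase, rose by 1.70 ± 0.18, and Abcc4, an export pump, by 2.97 ± 0.27. Slc22a7, an organic anion transporter, fell from 16.6 ± 8.99 to 1.27 ± 0.624 CPM (log2 fold change -3.73 ± 0.31, edgeR adjusted p = 4.47e-05). C9, a complement component, fell from 198 ± 95.5 to 43.5 ± 32.9 CPM (-2.45 ± 0.20).

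By group, 16 of 35 PPARα targets rose and 1 fell (22 and 1 adjusted over the list alone), with a set test adjusted p of 1.67e-16. The member that fell was Pdk4, an inhibitor of glucose oxidation, at -1.46 ± 0.33. Its call was lost without N984, N983, N972, N971, N980, N967, N988, N987 or N976. With an estimated correlation the adjusted p = 0.0833 for this list. Of 30 NRF2 targets, genes of antioxidant and glutathione metabolism, 12 rose and 0 fell (17 and 0 adjusted over the list alone; set test adjusted p = 6.70e-15, adjusted p = 0.121 with an estimated correlation). Of 29 peroxisomal genes 5 rose (10 rose and 1 fell adjusted over the list alone; set test adjusted p = 2.82e-05, adjusted p = 0.292 with an estimated correlation). Of 22 mitochondrial β-oxidation genes 2 rose, 5 adjusted over the list alone, with a set test adjusted p of 4.98e-07 (adjusted p = 0.292 with an estimated correlation). Among 30 genes of CAR and PXR xenobiotic metabolism 6 rose and 3 fell (11 and 5 adjusted over the list alone), including Gstm3 at 2.10 ± 0.34 and, in the other direction, Cyp3a41a at -6.65 ± 1.00 and Cyp3a44 at -6.18 ± 0.98, female-specific Cyp3a genes. Cyp3a41a was read at 2071 and 2730 CPM in the control females, 41.1 and 3.53 CPM in the 5% females and at most 0.197 CPM in any male. The call of Cyp3a44 was lost without N988 or N987. The median log2 fold change of that list was 0.30 and its mean -0.26. Its set test adjusted p was 0.0158, which became 0.0589 without N967, 0.0607 without N987 and 0.0616 without N975 (adjusted p = 0.364 with an estimated correlation).

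Interferon response genes were lower: 5 of 32 fell (12 fell and 1 rose adjusted over the list alone), among them Ifit3 at -1.53 ± 0.23 and Isg15 at -1.50 ± 0.23. The set test adjusted p was 2.01e-09 (adjusted p = 0.145 with an estimated correlation). Of 24 genes of one-carbon and amino acid metabolism 5 fell (11 adjusted over the list alone), among them Bhmt, which remethylates homocysteine, at -1.40 ± 0.23 (set test adjusted p = 8.13e-09, adjusted p = 0.121 with an estimated correlation). Of 29 acute phase genes 3 fell and 1 rose (9 and 1 adjusted over the list alone), and Orm1 fell by 1.08 ± 0.17 (set test adjusted p = 3.77e-05, adjusted p = 0.121 with an estimated correlation). The member that rose was Saa3, at 1.48 ± 0.34, a call lost without any of the libraries other than N983 and N975. Of 24 genes of gluconeogenesis and glycolysis 3 fell (8 fell and 1 rose adjusted over the list alone), among them Irs2, an insulin signalling adaptor, at -1.29 ± 0.23 (set test adjusted p = 0.000612, adjusted p = 0.121 with an estimated correlation). Of 16 periportal hepatocyte markers 1 fell, Ass1, a urea cycle enzyme, at -1.32 ± 0.21, against 5 fallen and 1 risen adjusted over the list alone (set test adjusted p = 6.02e-06, adjusted p = 0.218 with an estimated correlation). Of 20 hepatocyte secreted and core genes 1 fell, again Ass1, against 4 fallen and 1 risen adjusted over the list alone (set test adjusted p = 1.83e-05, adjusted p = 0.223 with an estimated correlation). Of 35 male-biased liver genes 5 fell and 1 rose (7 and 2 adjusted over the list alone; set test adjusted p = 0.00081, adjusted p = 0.218 with an estimated correlation). Of 23 markers of Kupffer cells and macrophages 0 passed the edgeR test, and 0 adjusted over the list alone, while the set test adjusted p was 0.00103 and the median log2 fold change -0.43 (adjusted p = 0.373 with an estimated correlation).

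**Figure D1:**
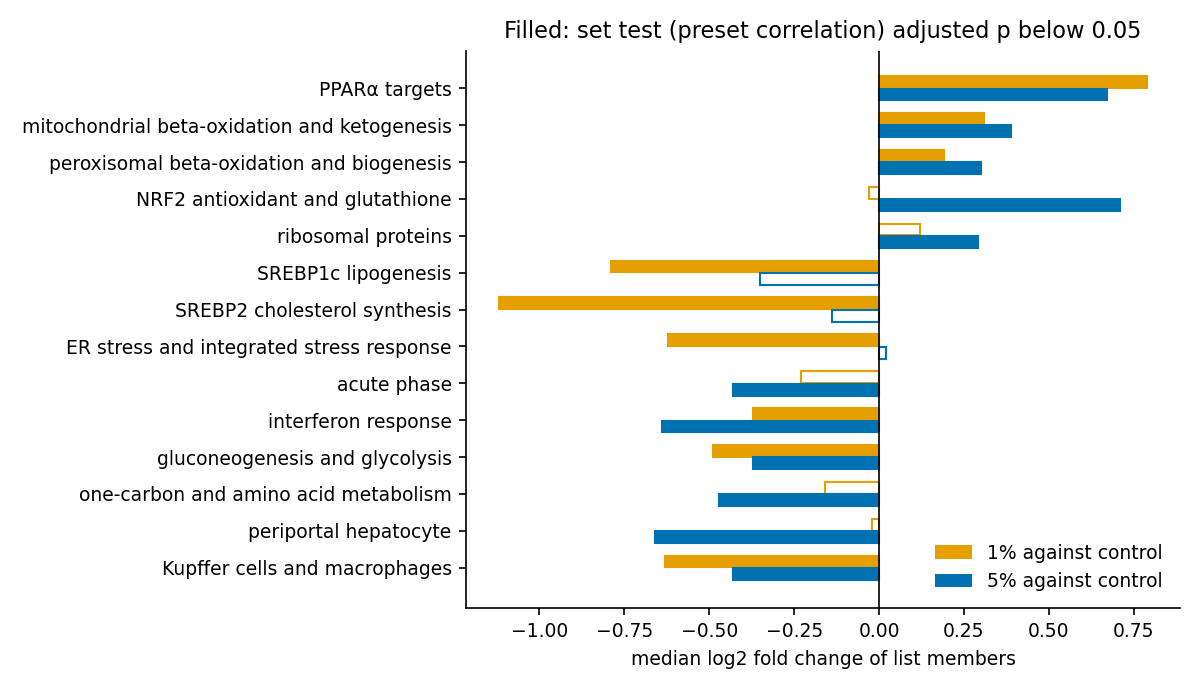
Median log2 fold change of the members of 14 gene lists (horizontal axis) for the 1% and 5% diets against control; filled bars mark a set test adjusted p below 0.05 at the preset correlation. The median of the PPARα targets was 0.67 at 5% and 0.79 at 1%, and that of the NRF2 targets 0.71 at 5% and -0.03 at 1%.

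Genes of the circadian clock were among the largest differences. Dbp, a clock output factor, rose from 0.566 ± 0.408 to 26.4 ± 11.3 CPM (log2 fold change 5.36 ± 0.83, edgeR adjusted p = 0.00919). Bhlhe41 and Per3, repressors of the clock, rose by 4.99 ± 0.59 and 3.27 ± 0.50, and Wee1, a clock-controlled kinase, by 3.2 ± 0.50. Bhlhe41 stood at 0 to 0.314 CPM and Dbp at 0.157 to 1.1 CPM in the controls, so their folds are fitted from few reads there. Npas2, an activator, fell by 3.31 ± 0.53 and Cry1 by 1.83 ± 0.26. Of 22 clock genes 8 rose and 4 fell (8 and 5 adjusted over the list alone), with a set test adjusted p of 0.011, which became 0.0616 without N975 (adjusted p = 0.176 with an estimated correlation). The labels give no hour of collection.

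**Figure D2:**
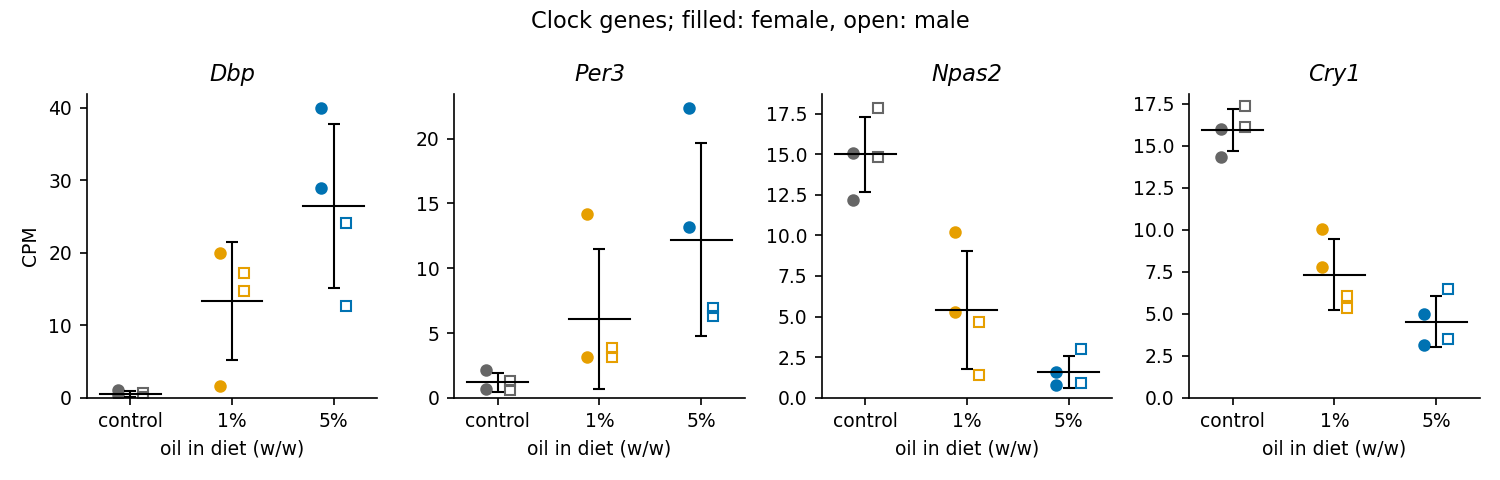
CPM of Dbp, Per3, Npas2 and Cry1 (vertical axes) in each liver by percent of oil in the diet (filled, females; open, males), with the mean and SD of the 4 livers per diet. Npas2 averaged 15.0 CPM in control, 5.41 CPM in 1% and 1.59 CPM in 5% livers.

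In all, 340 of 13814 genes passed, 164 higher and 176 lower at 5%. An unadjusted p below 0.05 was found for 2010 genes where chance gives 691. Of 41 lists, 9 were higher and 13 lower by the set test, 0 with an estimated correlation, and 13 by fry. Of 25 tested genes reported whatever their result, 19 did not pass. Their adjusted p ran from 0.0529 for Elovl5 to 0.986 for Fasn. Cyp7a1 (1.27 ± 0.49), Fgf21 (0.21 ± 0.58), Scd1 (-1.0 ± 0.40) and Fads2 (-0.83 ± 0.28) were among them. The count was 181 without N980, 179 without N968, 170 without N988, 193 without N987 and 138 without N976. With a score of clock genes in the design 0 genes passed, and 9 of 74 named genes past the threshold changed sign. Clock scores ran from -2.67 to -1.30 in controls and from 0.629 to 2.42 in 5% livers, so that score and diet nearly coincide. The score was made after the data were seen, from part of the clock list, with Dbp, Bhlhe41, Per3, Npas2 and Cry1 among its genes. Its separation of the diets is thus partly fixed by that choice, and the loss of calls with it does not show a cause.

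**Figure D3:**
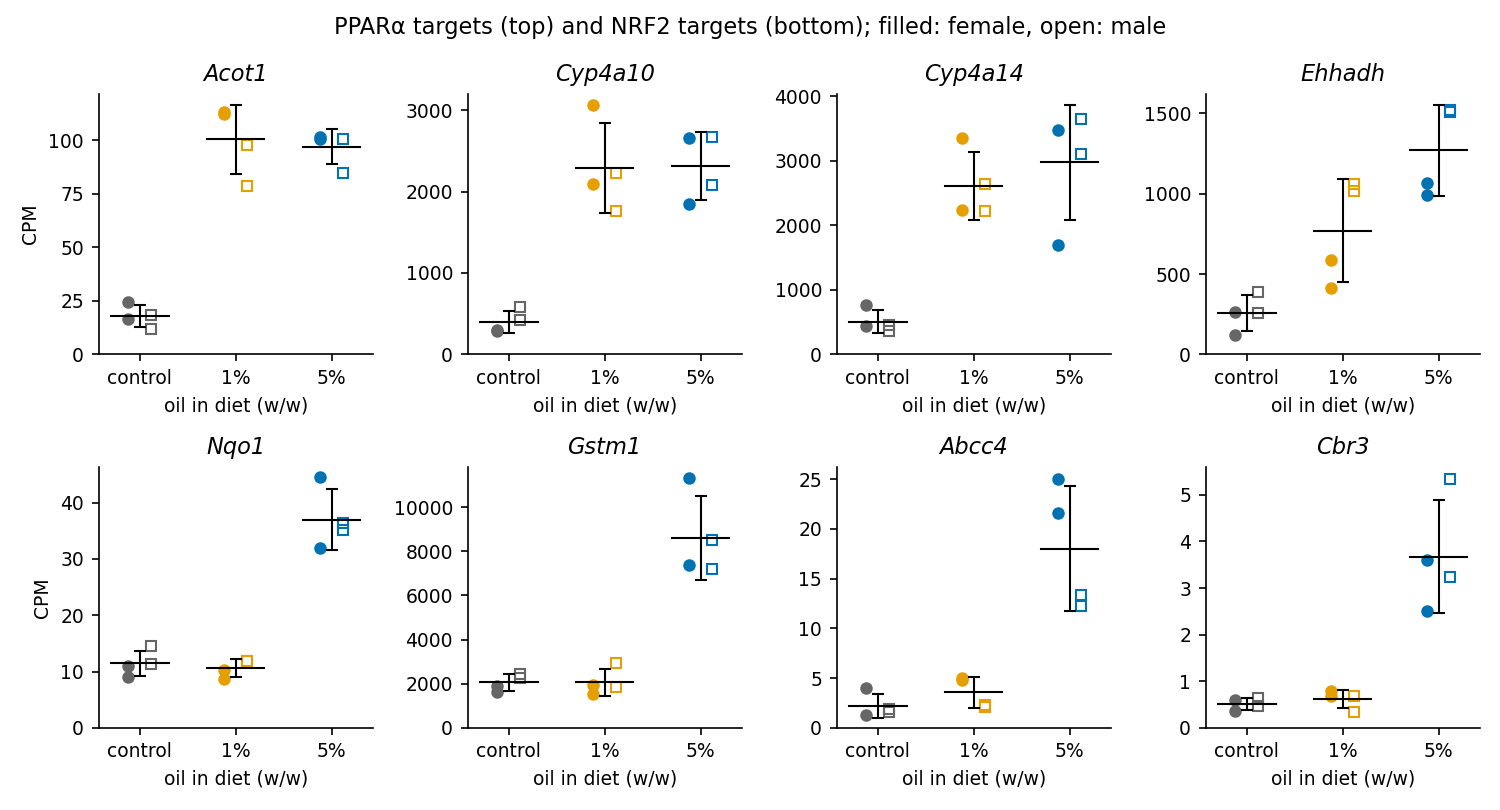
CPM of PPARα and NRF2 target genes (vertical axes) in each liver by percent of oil in the diet (filled, females; open, males), with the mean and SD of the 4 livers per diet. Acot1 averaged 17.9 CPM in control, 100.5 CPM in 1% and 97.1 CPM in 5% livers, while Nqo1 averaged 11.5 CPM, 10.6 CPM and 37.0 CPM.

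The 1% diet against control asks whether the lower dose acts on the liver. Several PPARα targets rose at this dose too: Acot1 went from 17.9 ± 5.16 to 100.5 ± 16.2 CPM (n = 4 per diet, log2 fold change 2.50 ± 0.19, edgeR adjusted p = 3.02e-05). Cyp4a10 rose by 2.55 ± 0.26, Cyp4a14 by 2.37 ± 0.28, Cyp4a31 by 2.48 ± 0.27 and Acot2 by 1.87 ± 0.23. Of 35 PPARα targets 7 rose and 0 fell (23 rose and 1 fell adjusted over the list alone; set test adjusted p = 8.63e-22). This was the list whose call held with an estimated correlation (adjusted p = 0.0355). Other increases were Smad9, a signal transducer, at 3.04 ± 0.42, Krt23, a keratin, at 2.91 ± 0.39, and Nlrp12 at 1.90 ± 0.23. NRF2 targets did not pass at 1%, with 0 of 30 past the edgeR threshold and 0 adjusted over the list alone; Nqo1 stood at -0.10 ± 0.18, and the set test adjusted p was 0.605.

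Of 25 SREBP2 targets, genes of cholesterol synthesis, 2 fell at 1% (16 adjusted over the list alone). The set test adjusted p was 7.33e-15, but 0.337 with an estimated correlation, 0.119 by fry and 0.0989 with the clock score. Of 26 SREBP1c targets, genes of fatty acid synthesis, 0 passed the edgeR test over all genes and 12 were lower adjusted over the list alone (set test adjusted p = 1.53e-09, adjusted p = 0.337 with an estimated correlation and 0.126 by fry). Fasn, fatty acid synthase, stood at -2.09 ± 0.49 (edgeR adjusted p = 0.123) and Elovl6 at -2.24 ± 0.65 (0.237), neither past the threshold. Control N979 lay near the 1% livers in both. Its Fasn was 587 CPM, against 243 to 568 at 1% and 1822 to 2480 in the other controls. Its Elovl6 was 90.3 CPM, against 87.1 to 152 and 497 to 897. Of 27 ER stress genes 1 fell, Eif2ak3, at -1.30 ± 0.21, against 13 adjusted over the list alone (set test adjusted p = 1.25e-10, adjusted p = 0.133 with an estimated correlation). Its call was lost without N984, N972, N980, N968 or N967. Abtb2 fell by 1.58 ± 0.19. Interferon genes had 0 of 32 past the edgeR threshold and 3 lower adjusted over the list alone. Their set test adjusted p was 9.20e-06, but 0.337 with an estimated correlation and 0.126 by fry. Markers of Kupffer cells and macrophages had 0 of 23 past the edgeR threshold, 2 lower adjusted over the list alone and a median log2 fold change of -0.63. Their set test adjusted p was 4.15e-05, but 0.337 with an estimated correlation and 0.15 by fry. Of 20 genes of inflammatory cytokines 0 passed, 0 adjusted over the list alone (set test adjusted p = 0.00751, adjusted p = 0.337 with an estimated correlation). That set test adjusted p became 0.0607 without N980, 0.201 with the noncoding share in the design and 0.0542 with the clock score.

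In all, 31 genes passed at 1%, 19 higher and 12 lower, with 1530 at an unadjusted p below 0.05 where chance gives 691. By list, 4 were higher and 8 lower by the set test, 3 by fry. As many lists passed the set test in 16 of 35 splits of the same livers, the real one included, so chance cannot be excluded for these lists. Of the 25 genes reported whatever their result 19 did not pass, with log2 fold changes from -2.48 for Sqle to 0.52 for Elovl3. That of Sqle was -0.73 without N980 and 0.68 with the clock score in the design. The count was 13 without N984, 14 without N972, 184 without N979, 19 without N968, 20 without N967, 56 without N987 and 53 without N975. DESeq2 called 277, and 1 gene passed with the clock score in the design. The 1% females N983 and N984 and male N971 also held a larger share of long noncoding reads (1.06% to 1.83%) than 3 of the 4 controls (0.611% to 0.726%). Above 0.8% the only control was N979, where 16 genes passed, so that fit cannot part the diet from that liver.

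The 5% diet against the 1% diet tests the difference between the doses. NRF2 targets were higher at 5%: Gstm1 by 2.09 ± 0.23 (edgeR adjusted p = 0.000857, n = 4 per diet) and Abcc4 by 2.37 ± 0.25. Of 30, 11 rose with 0 lower (21 adjusted over the list alone; set test adjusted p = 1.20e-16, adjusted p = 0.286 with an estimated correlation). Ugt2b35, a glucuronosyltransferase, was higher by 1.97 ± 0.27, and Slc22a7 lower by -2.74 ± 0.31. PPARα targets did not separate the doses: 0 of 35 passed the edgeR test (3 higher and 1 lower adjusted over the list alone), the median log2 fold change was 0.01, and the set test adjusted p was 0.726. Of 27 ER stress genes 7 rose from 1% to 5% (12 adjusted over the list alone; set test adjusted p = 1.30e-06, adjusted p = 0.286 with an estimated correlation). Of 25 SREBP2 targets 2 rose (6 adjusted over the list alone; set test adjusted p = 1.22e-08, adjusted p = 0.488 with an estimated correlation). Of 35 male-biased genes 4 fell (10 fell and 1 rose adjusted over the list alone; set test adjusted p = 7.13e-05, adjusted p = 0.286 with an estimated correlation). In all 184 genes passed, 119 higher and 65 lower at 5%. The count was 15 without N984, 39 without N983, 47 without N972, 13 without N971, 385 without N979, 74 without N968, 97 without N967, 70 without N988, 34 without N987, 16 without N976 and 597 without N975. It was 61 with the noncoding share in the design and 50 with a surrogate variable.

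Along the dose, with the percent of oil as a number, the slope of Abcc4 was 0.59 ± 0.04 log2 units per percent (edgeR adjusted p = 2.59e-05, n = 12) and that of Slc22a7 -0.73 ± 0.06 (3.59e-05). Gsta2, a glutathione transferase, had a slope of 0.61 ± 0.09, Csad, an enzyme of taurine synthesis, 0.46 ± 0.07, Tsku, a secreted liver protein, 0.53 ± 0.07, and Ntrk2, a neurotrophin receptor, -0.92 ± 0.13. In all 308 genes passed, 168 rising and 140 falling with the percent of oil. The count was 195 without N983, 194 without N972, 182 without N979, 198 without N968, 88 without N988, 103 without N987 and 80 without N976, and 616 with the noncoding share in the design.

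The doses share some genes. Of the 164 genes higher at 5% and the 19 higher at 1%, 14 were in both (0.226 if the calls were independent, 7.08 in simulations with shared controls and no effect), among them Acot1, Cyp4a10, Cyp4a14 and Ehhadh. Of the 176 lower at 5% and the 12 lower at 1%, 6 were in both (0.153 if independent, 2.60 simulated), among them Lrtm1. The simulated overlaps are of as many top genes by p, whether past the threshold or not, and are given without their spread. Simulations averaged 0.025 genes past the threshold at 5%, so the simulated and observed overlaps are not of the same kind. At 1% the call of Ehhadh was lost without N984, N972 or N968, and that of Lrtm1 without N984 or N968. Both comparisons use the same 4 control livers, and simulated diets without effect gave the same sign at 1% for 95.6% and 91.9% of as many top genes, against 87.8% and 93.8% observed for higher and lower genes at 5%. Across genes, which are not independent replicates, the fold changes of the doses had r = 0.429 and rho = 0.338, against 0.523 and 0.485 simulated from the shared controls alone. The jackknife SE of that r over libraries was 0.177. Their covariance was 0.153 against a simulated 0.0866, a difference of 0.066. Its error is not known, since genes were simulated independently of each other. With the controls divided between the doses, 1 female and 1 male each, r was 0.129, 0.214, 0.0493 and, with the 5% livers against N979 and N968, -0.127, and the covariance ran from -0.0792 to 0.0942.

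Both sexes were fed each diet, which asks whether they respond alike. In females 255 genes passed for 5% against control, 118 higher and 137 lower, and in males 25, 13 higher and 12 lower, with 2 animals against 2 in each sex. Of these 17 were shared, all in the same direction (0.461 if independent), and 225 of the 255 female calls (88.2%) had the same sign in males. No difference in response passed the edgeR test: 0 genes for the 5% diet, with 645 at an unadjusted p below 0.05 where chance gives 691, 43 by DESeq2 and 0 by limma voom. For the 1% diet 0 genes passed, with 517 unadjusted, 6 by DESeq2 and 0 by limma voom. The smallest p values for the 5% diet belonged to Gprc5b, whose response was higher in females by 4.77 ± 0.66 (edgeR adjusted p = 0.114), and Mup10, lower by -4.53 ± 0.65 (0.114). For the 1% diet Tsku stood at 2.27 ± 0.34 (0.314). None of these passed. In simulations the test found 16% of genes with a 4-fold difference in the response to the 5% diet, so a smaller difference was mostly not detectable at this size. The female count was 78 without N988 and 101 without N987. It was 395 above the noncoding split, where 1 library (N988) stood against 1 (N979), and 556 below it, N987 against N980. The male count was 16 without N984, 16 without N983, 64 without N980, 57 without N979, 0 without N968, 3 without N967, 2 without N976 and 5 without N975. For the 5% difference between the sexes it was 1 without N980, 2 without N979 and 1 without N987, and for the 1% difference 2 without N972 and 1 without N979.

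Females were compared with males over all diets (n = 6 per sex). Genes known as sex-biased in mouse liver led: Cyp3a41a was higher in females by 13.46 ± 0.95 on the log2 scale, and Cyp4a12a and Cyp4a12b lower by -10.38 ± 0.60 and -9.71 ± 0.36 (edgeR adjusted p = 1.48e-05, 1.60e-06 and 3.92e-09). These folds are fitted from few reads in the lower sex. Of 27 genes listed as female-biased 22 were higher and 0 lower (24 adjusted over the list alone). Of 35 listed as male-biased 28 were lower and 0 higher (31 adjusted over the list alone). Both set tests held with an estimated correlation (adjusted p = 0.00436 and 0.00222). Adipocyte markers were lower in females in 4 of 6 cases, also adjusted over the list alone, Cidea by -9.83 ± 1.07, and this call held as well (adjusted p = 0.0395 with an estimated correlation). The list does not measure adipocytes alone: Cidec is also listed as a PPARα target, and Car3 stood at 758 CPM or more in every liver. Of 37 ribosomal protein genes 17 were higher in females (32 adjusted over the list alone; set test adjusted p = 7.06e-13, adjusted p = 0.438 with an estimated correlation). Of 29 acute phase genes 9 were higher (11 adjusted over the list alone; set test adjusted p = 0.00066, adjusted p = 0.182 with an estimated correlation). Of 29 peroxisomal genes 10 were lower (13 lower and 3 higher adjusted over the list alone; set test adjusted p = 0.000144, adjusted p = 0.438 with an estimated correlation). In all 1235 genes passed, 497 higher and 738 lower in females. The count was 676 without N984, 695 without N983, 641 without N972, 2356 without N980, 765 without N979, 775 without N968, 594 without N967, 636 without N988, 1942 without N987 and 689 without N976, and 495 with the noncoding share in the design.

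The authors' deposited table lists 261 genes, 161 higher and 100 lower, of which 139 have an adjusted p below 0.05 and 258 below 0.1 there. Its log2 fold changes followed the mean of both oil diets against control (r = 0.998 across genes), a contrast added here after the data were seen, in which Acot1, Cyp4a10 and other genes enter from both doses; all 261 had the same sign. In that contrast 179 genes passed by edgeR, 71 higher and 108 lower, and 131 of the 261 were among them, while 168 passed at 5% and 26 at 1%. The 179 became 85 without N980, 66 without N968, 110 without N967 and 119 without N988, and 0 with the clock score in the design.

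Libraries differed in long noncoding reads across the diets. Their share was 1.83% of gene reads in 1% female N984, 1.47% in 1% female N983, 1.06% in 1% male N971, 1.55% in control female N979, 1.14% in 5% female N988 and 0.923% in 5% male N975, and from 0.611% to 0.726% in the other 6 livers. Neat1, a nuclear noncoding RNA, ranged from 150.3 to 1171 CPM without the TMM factors. The first 2 principal components held 35.8% and 16.7% of the variance.

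**Figure D4:**
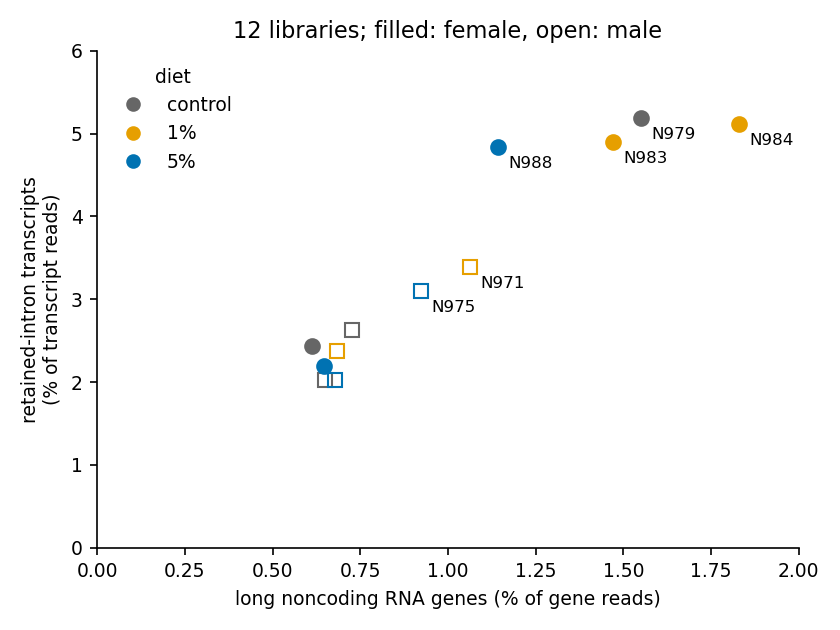
Share of gene reads in long noncoding RNA genes (horizontal axis, percent) against the share of transcript reads on retained-intron transcripts (vertical axis, percent) in each of the 12 livers, colored by diet. The 6 livers above 0.8% on the horizontal axis lie between 3.10% and 5.19% on the vertical axis, and the other 6 between 2.02% and 2.62%.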

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

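Of the tests here, those on equal read numbers and on the coding transcript of Lars2 were chosen after the result was seen, and the grouping by noncoding share was made from the data. In 5 of 30 pairs of a library measure and a diet (10 measures, 3 diets) a liver lay far from the other 3 of its diet, where chance gives about 1 in 20 pairs. Ribosomal RNA took 7.65% of transcript reads in control female N979 and 0.384% in 5% male N975. Lars2, a mitochondrial leucyl-tRNA synthetase gene, took 2.54% of gene reads in N979. Long noncoding RNA took 1.55% of gene reads in N979, the highest control. Alb took 13.1% of gene reads in control female N980.

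Of 12 livers, 6 held more long noncoding reads, 0.923% to 1.83% against 0.611% to 0.726% of gene reads, and both kinds occur in each diet, though both control males lay below and both 1% females above. Depth does not account for the gap, since at 5291240 reads in every library the lowest of the 6 still showed 578 genes more than the highest of the others. Genomic DNA, at the rate seen in 1752 olfactory and other receptor genes that liver does not use, would supply 4.99% of the added noncoding reads. Retained-intron transcripts took 3.10% to 5.19% of transcript reads in the 6 and 2.02% to 2.62% in the others, a gap of 0.477 percentage points. Unspliced or nuclear RNA may thus have entered these libraries in a larger share. The excess was uneven over genes. Gm43305, a long noncoding gene, stood at 1205 to 6832 CPM in the 6 and 394.4 to 819.2 CPM in the others. The gain over all long noncoding genes, as used for the DNA rate, was 6410 CPM. BC024386 also lay higher, at 263 to 676.4 against 119.6 to 185.4 CPM, while AC160336.1 overlapped. Gm43305 thus weighs heavily in the noncoding share, which was not recomputed without it. No biological explanation was tested. In 1% against control 3 of the 4 noncoding-rich livers were on the diet, and with the noncoding share in the design 29 genes passed there against 31.

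In N979 ribosomal RNA and Lars2 stood out together. A higher expression of the whole Lars2 gene is argued against by its longest protein-coding transcript. It stood at 10.3 CPM in N979, within the 3.09 to 24.6 CPM of the other livers (CPM without the TMM factors). In N979 another of the 9 Lars2 transcripts took 99.96% of the Lars2 reads. That other transcript took most of them in every liver, for example 1083 of 1245 in N967. Its amount set N979 apart, at 134300 reads against at most 13690 elsewhere. Ribosomal sequence shared with that transcript could still be a source: 0 words of 31 bases were shared with the annotated ribosomal RNA, but the annotation searched holds 2496 bases of it, a small part of the ribosomal precursor, so the absence of shared words does not exclude it. No biological explanation was tested.

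The 5% effect differed between the sexes in 11 lists by the preset-correlation set test of the interaction, 0 of them with an estimated correlation and 0 by fry. It was higher in females for mitochondrial β-oxidation (adjusted p = 0.000234), SREBP1c targets (0.00182), NRF2 targets (7.80e-05), cell cycle genes (3.42e-05), B and plasma cells (0.00552) and neutrophils (4.76e-05). It was lower in females for SREBP2 targets (4.43e-07), hepatocyte core genes (0.0019), female-biased genes (7.93e-05), male-biased genes (0.000564) and liver endothelial cells (3.13e-07).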

How the results depend on the processing

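The covariates for noncoding reads and clock genes, the fits on part of the libraries by noncoding share, and all fits of both oil diets against control were chosen after the data were seen. Of 147 named-gene results past the threshold, 72 stayed past it with RLE factors, DESeq2, limma voom, the noncoding share in the design and each library left out, 75 with each library left out. In these fits 0 of them changed sign, while 12 of the 48 not past it did. With the clock score in the design 0 of 74 named genes stayed past the threshold for 5% against control and 1 of 21 for 1%. At 5% 9 of them then changed sign, to log2 fold changes of -0.75, -0.54, -0.40, -0.29, -0.05, 0.16, 0.33, 0.42 and 1.03, none past the threshold there. Of 34 set test calls at the doses 24 held with each library left out. The cause of the changes below was not tested unless stated. No paired analysis was possible because the animals' numbers differ between groups. Spread between animals and depth limit what can be seen: in simulation 37.8% of 2-fold and 83% of 4-fold changes were found for 5% against control.

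Counts follow in the order 5% against control, 1% against control, 5% against 1%, trend, female against male, 5% in females, 5% in males and both oil diets against control, against 340, 31, 184, 308, 1235, 255, 25 and 179. With no filter they were 1011, 649, 1276, 1108, 2375, 881, 323 and 753, and the differences between the sexes gave 229 genes at 5% and 109 at 1%. With DESeq2 they were 749, 277, 707, 733, 2079, 666, 145 and 468, and 43 and 6 for those differences. At an adjusted p of 0.1, which admits more genes by construction, they were 637, 111, 519, 572, 2416, 561, 43 and 328. With the noncoding share in the design the first was 632, 1% against control 29, 5% against 1% 61, the trend 616, the sexes 495, 5% in females 712, 5% in males 85 and the 5% difference between the sexes 7. Arms of 1 library stand in the fits split by noncoding share, so they do not test diet apart from single livers. Below the split the 1% arm was N972 alone, the 5% females were N987 against control N980, and the 5% males were N976 alone. Above it the control arm was N979 alone. In the 6 libraries below the split 5% against 1% gave 15, the sexes 164, 5% in females 556, 5% in males 303 and the 5% difference between the sexes 75. In the 6 above it 5% against control gave 75, 1% against control 16, 5% against 1% 61, the trend 114, the sexes 258, 5% in females 395 and both oil diets 30. With the clock score in the design 5% against control gave 0, 1% against control 1 and both oil diets 0. Without a sex term the first 4 were 107, 10, 8 and 124, and without a diet term the sexes gave 719. With a surrogate variable 5% against control gave 660, 5% against 1% 50 and the trend 598. With only the libraries compared the first 3 were 201, 53 and 306. With 6 groups averaged the trend gave 477. With a 2-fold minimum, stricter by construction, the trend gave 193 and the sexes 465. With the stricter filter 1% against control gave 50.

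Limma trend on the deposited CPM gave 54 for 1% against control, 281 for 5% against 1% and 384 for 5% in females. That table has no TMM factor, and with it the median of all genes moved to 0.175 for 5% against control, 0.103 for 5% against 1%, 0.192 for 5% in females, 0.161 in males and 0.122 for both oil diets. Higher and lower genes were then 340 and 118 (against 164 and 176) for 5% against control, 228 and 53 (119 and 65) for 5% against 1%, 340 and 95 (168 and 140) for the trend, 700 and 601 (497 and 738) for the sexes, 269 and 115 (118 and 137) for 5% in females, 13 and 7 (13 and 12) in males and 124 and 56 (71 and 108) for both oil diets. With upper-quartile factors they were 81 and 76 for 5% against 1%, 145 and 170 for the trend, 637 and 592 for the sexes and 9 and 11 for 5% in males, where RLE factors gave 12 and 12.

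Of the lists, 22 at 5% became 0 with an estimated correlation and 13 by fry. At 1% 12 became 1 with an estimated correlation and 3 by fry. With the clock score 14 lists passed at 5%, but some of these were not among the 22. Calls lost with it included mitochondrial β-oxidation (set test adjusted p = 0.968), peroxisomal genes (0.754) and NRF2 targets (0.159). The ribosomal protein list, higher at 5%, was lower with the clock score in the design (adjusted p = 0.00574). The correlation between the doses, 0.429, became 0.129, 0.214, -0.127 and 0.0493 with divided controls.

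With each library left out the counts ran from 138 to 479 for 5% against control, 13 to 184 for 1% against control, 13 to 597 for 5% against 1%, 80 to 424 for the trend and 594 to 2356 for the sexes. They ran from 0 to 2 for each difference between the sexes in response, 78 to 295 for 5% in females, 0 to 64 in males and 66 to 214 for both oil diets. Lists ran from 18 to 26 at 5% and 10 to 15 at 1%, and the correlation between the doses from 0.393 to 0.562.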

Other observations

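The tests of the hour of collection and of the clock score on the PPARα list, the noncoding share as a covariate and the comparison with other splits were chosen after the result was seen. At 5% against control other genes also changed. Tsku rose by 2.76 ± 0.40 on the log2 scale, Adgrg2, an adhesion receptor, by 2.76 ± 0.34, and Cyp2a4, a female-biased cytochrome, by 2.69 ± 0.42 (edgeR adjusted p = 0.00572, 0.00117 and 0.00712, n = 4 per diet). Loxl4, a lysyl oxidase, fell by 3.47 ± 0.44 and Serpina12, a male-biased gene, by 3.46 ± 0.54. Gadd45a, a stress gene, rose by 3.48 ± 0.58, a call lost without N980. Of 6 AhR targets 1 rose, Nqo1 (3 adjusted over the list alone; set test adjusted p = 0.000277, adjusted p = 0.121 with an estimated correlation). Of 7 erythroid genes 1 fell, Alas2 (1 adjusted over the list alone; set test adjusted p = 0.00814, adjusted p = 0.364 with an estimated correlation), a gene call lost without N968 or N976. Of 16 liver endothelial markers 0 passed the edgeR test and 0 adjusted over the list alone, with a median log2 fold change of -0.40 and a set test adjusted p of 0.00199, which became 0.0678 without N980 and 0.0840 without N988 (adjusted p = 0.373 with an estimated correlation). Of 37 ribosomal protein genes 0 passed and 0 adjusted over the list alone, while the median was 0.29 and the set test adjusted p 6.67e-08. That list gave an adjusted p of 0.373 with an estimated correlation and 0.0907 by fry, and was lower instead with the clock score in the design (0.00574).

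Between the sexes, 3 of 13 mitochondrially encoded genes were lower in females (10 adjusted over the list alone; set test adjusted p = 5.41e-05, adjusted p = 0.438 with an estimated correlation). Noncoding-rich livers were unevenly spread, 4 of 6 females and 2 of 6 males. Mitochondrial genes took the smallest shares of gene reads in the noncoding-rich females N979 (5.51%) and N988 (5.93%). The noncoding-rich females N984 (7.92%) and N983 (10.2%) lay higher, against 7.24% in N987 and 8.43% in N980. The noncoding-rich males N975 (9.88%) and N971 (10.6%) lay above N976 (9.36%), which was not noncoding-rich. Within each sex the shares overlapped, so a link between noncoding share and this list is not shown. Of 27 ER stress genes 9 were lower in females (12 adjusted over the list alone; set test adjusted p = 6.18e-06, adjusted p = 0.245 with an estimated correlation). Of 30 NRF2 targets 9 were lower and 1 higher in females (14 and 3 adjusted over the list alone; set test adjusted p = 0.000194, adjusted p = 0.438 with an estimated correlation).

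The clock genes differed between control and 5% livers. Noncoding-rich libraries do not account for it, since 11 of 12 clock genes past the threshold still passed with the noncoding share in the design. A different hour of collection or last meal may account for it: Dbp, Tef, Hlf, Nr1d1, Nr1d2, Per3, Ciart and Bhlhe41 averaged 2.59 and Arntl, Npas2, Clock, Cry1 and Nfil3 -1.88, a difference of 4.47 on the log2 scale, but the labels give no hour, so this and an effect of the oil on the clock cannot be told apart. At 1% these groups averaged 2.01 and -0.95. The same genes make up the clock score and were chosen from the clock list after the data were seen. The size of their difference is thus partly fixed by that choice. With the clock score in the design the mean difference of the PPARα list was 0.73 ± 0.29 (SE) against 0.92 ± 0.10 without it, more than 2 SE above 0, so for this list the clock score did not take up the whole difference. The set tests of mitochondrial β-oxidation (adjusted p = 0.968), peroxisomal genes (0.754) and NRF2 targets (0.159) no longer passed with it. Nor did those of CAR and PXR genes (0.962), AhR targets (0.253), gluconeogenesis and glycolysis (0.253), male-biased genes (0.253), Kupffer cells (0.443), endothelial cells (0.159) or the clock genes themselves (0.159). Acot1 moved from 2.46 ± 0.18 to 2.65 ± 0.47, a larger standard error rather than a smaller fold, the score raising the variance of the diet term 7.73 times. Pdk4 moved from -1.46 ± 0.33 to 0.33 ± 0.80. The NRF2 list moved from 1.00 ± 0.15 to 0.38 ± 0.36 and Gstm1 from 2.09 ± 0.23 to 0.78 ± 0.46, so for these a share of the clock or hour in the difference stays open.

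The livers were also divided into other groups of the same sizes. For 5% against control 1 of 35 splits, the real one, gave as many as 340 genes, and the highest other gave 0. That is the smallest share 35 splits can give. The splits were made without regard to sex, so many did not keep 2 females and 2 males per group as the diets do. Those partly follow the sex term, which can lower their counts, so fewer than 35 are like the real one. The other splits also mix the diets, which adds any diet difference to their spread and can lower their counts. Chance is therefore not excluded. For its lists 1 of 35 gave as many as 22, the highest other being 19 and the median of the others 11. Chance is not excluded for that count, which lay close to 19, nor for single lists. The other splits also called many, and 0 passed with an estimated correlation. For 1% against control 2 of 35 splits gave as many as 31 genes, the highest other giving 66, so chance cannot be excluded. That split set the 4 noncoding-rich livers N984, N983, N971 and N979 against the rest, a structure of the samples. For the 1% lists 16 of 35 splits gave as many as 12, the highest other giving 20 and the median of the others 11, so chance cannot be excluded. For 5% against 1% 1 of 35 splits gave as many as 184 genes, the highest other giving 1. For the trend 1 of 100 splits drawn gave as many as 308, the highest other 34, and for the sexes 1 of 100 gave as many as 1235, the highest other 10. For both oil diets against control 1 of 100 gave as many as 179, and the highest other, 102, again set 4 noncoding-rich livers apart. For these 4 the real grouping alone reached its count, and 1 of 35 and 1 of 100 are the smallest shares possible. These splits did not keep diet and sex balanced either, so chance is not excluded by them.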
